A study of Arabidopsis thaliana with 6 samples.

How the data were processed

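RNA from rosette leaves of Arabidopsis thaliana was measured on 6 Affymetrix ATH1 arrays, 3 of the pho3 line and 3 of its wild-type background Ws-2. The submitters' processing notes name MAS5, without a version, and the deposited signal intensities fit its usual output in scale. Per the file headers and the values themselves, the deposited table holds 1 linear signal intensity per probe set and array. The mean after trimming 2% at each end was 100.0 on every array, rounded to 1 decimal. A MAS5 signal is a robust average over the probe pairs of a probe set, and dim probe sets carry the largest relative error on this scale. Detection calls were not used here.

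Each array was assigned to its group and replicate number from its title. The labels do not say whether replicates came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical. The array holds 22810 probe sets. The 64 control probe sets were left out of the gene tests. Of the other 22746, the 13983 with a signal at or above their array's 40th percentile on at least 3 arrays were tested. The percentile lay between 26.2 and 28.4 on the 6 arrays. The number of arrays limits the precision.

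Signals were logged to base 2 with no pseudocount and no further scaling. Differences were pho3 minus wild type. They were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Gene lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, each adjusted over the 13 lists tested. The scripts were tested on simulated data. With the spread of the fit to all 6 arrays, 52% of 50 probe sets changed 2-fold and 96% of 50 changed 4-fold were called among 13983. With the spread of the fit without wild-type replicate 1, the shares were 64% and 96%. Both simulations used 3 against 3 arrays, with noise drawn independently for each probe set. The shares test the scripts and are not the power in these data, where whole arrays deviate together. Nor are they the power of the fit without wild-type replicate 1. Principal components, pairwise spreads and figures were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

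Gene names came from the platform annotation of the array, updated through gene numbers to the RefSeq table of assembly TAIR10.1. In it 13513 probe sets had 1 gene, 503 had several and 8730 were unlisted and stay unnamed here. Of the single-gene probe sets, 13436 matched the RefSeq table. No probe set with several genes was used to name a gene. No coordinates are given, because the build behind the probe annotation is not given in the sources used here.

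The design, the 26 gene lists and the rule for named genes were fixed before the data were examined. The lists hold 403 different genes, of which 62 had a probe set of their own with a name and 59 were tested. No tested member matched by locus carried the name of another gene. The lists cover phenylpropanoid entry, flavonoid enzymes and regulators, starch synthesis and breakdown, sucrose metabolism and sugar transport, photosynthetic light reactions, the Calvin cycle, photorespiration, chlorophyll synthesis, glycolysis, the oxidative pentose phosphate pathway, plastid translocators, phosphate starvation, nitrogen assimilation, sugar starvation, salicylic acid, jasmonate, abscisic acid and cold, leaf senescence, and markers of phloem, xylem, flower, seed, guard cell and root. The rule named the 10 genes with the largest change in each direction among those past the threshold with groups that did not overlap. It also named up to 4 members of each list with the smallest adjusted p and the member that most opposed the rest. It further named 11 genes whatever their values, of which APL3 and DFR are named on the array table used here. SUC2, GPT2, MYB75, MYB90, LDOX, CHS, BAM5, RBCS1A and LHCB1.4 are unnamed here and have no value. Where the dimmer group lay under the 40th percentile, a fold is given as at least the bright mean over that percentile. All folds are ratios of geometric means, taken from differences between means of log2 signals, while levels printed as averages are arithmetic means.

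The alternatives tried were quantile normalization, median centring, a pseudocount of 16, other filters, other variance priors, array weights, the replicate number as a block and leaving out each array in turn. A fit without both wild-type replicate 1 and pho3 replicate 3, the estimated correlation with each array left out in turn, and the use of the naming rule on the fit without wild-type replicate 1, were added after the data had been seen.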

Results

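Transcript levels were measured in rosette leaves of pho3, an Arabidopsis line from the Feldmann T-DNA insertion collection, and of the wild-type accession Ws-2. There were 3 arrays per group. Plants were grown at 23 °C with 16 h of light and 8 h of dark, for 10 days on medium with 1% sucrose and then on compost, to growth stage 6.0. Each array gave a linear signal for 22810 probe sets, with a median signal between 40.4 and 44.3. From background knowledge, pho3 carries a defect in SUC2, the sucrose transporter that loads the phloem. The probe set of SUC2 is unnamed here, so the insertion could not be checked against the labels.

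The array labelled wild-type replicate 1 stood apart from the other wild-type arrays. DFR, dihydroflavonol reductase of anthocyanin synthesis, had signals of 736, 1155 and 586 on pho3 replicates 1, 2 and 3. It had 799 on the array labelled wild-type replicate 1, against 34.2 and 27.6 on wild-type replicates 2 and 3. The APL4 subunit of ADP-glucose pyrophosphorylase, the entry enzyme of starch synthesis, had 458, 488 and 216 in pho3 and 372, 16.3 and 16.1 in wild type. For both genes that array read within the pho3 range and wild-type replicates 2 and 3 far below it. Over the 13983 probe sets tested, the spread of log2 differences between arrays (scaled median absolute deviation) was 0.31, 0.31 and 0.27 for that array against pho3 replicates 1, 2 and 3. It was 0.48 and 0.47 against wild-type replicates 2 and 3. The array labelled pho3 replicate 3 lay between the groups, at 0.43 and 0.44 from pho3 replicates 1 and 2 and 0.35 and 0.37 from wild-type replicates 2 and 3. Directions below follow the labels as given.

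**Figure D1:**
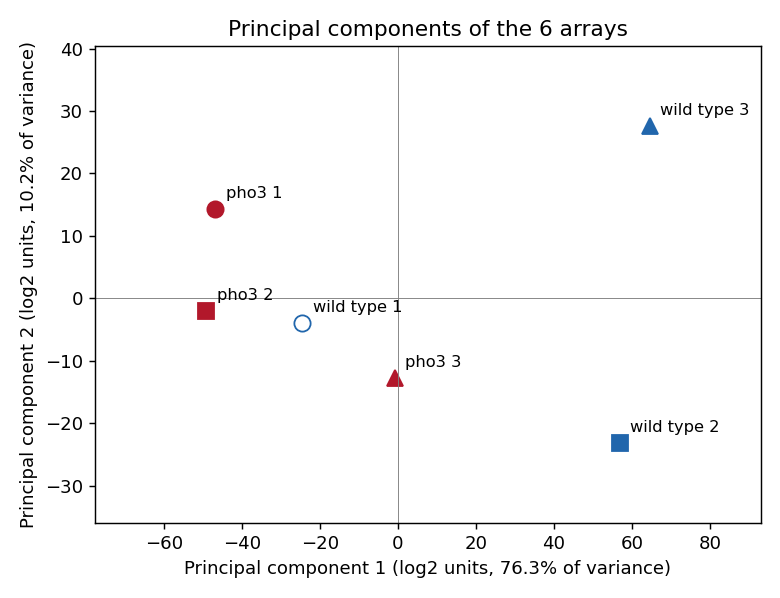
Each point is 1 array on the first 2 principal components of log2 signal over the tested probe sets (axes in log2 units, with the percent of variance). Red marks pho3 and blue wild type, circles, squares and triangles are replicates 1, 2 and 3, and the open circle is the array labelled wild-type replicate 1, which lies at -24.5 on component 1 while wild-type replicates 2 and 3 lie at 56.9 and 64.6.

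The first comparison asked which genes differ between pho3 and wild-type leaves. Genes of anthocyanin synthesis were higher in pho3 as a list, as were starch synthesis and leaf senescence genes. Genes of the light reactions, the Calvin cycle and photorespiration were lower as lists. None of these 6 list calls held with an estimated correlation (adjusted p = 0.605 for each) or with fry (adjusted p = 0.321 for each). The lists cover only part of each pathway, as members without a named, tested probe set have no value here. Tested, and called measured below, were 6 of 18 anthocyanin, 3 of 18 starch synthesis and 3 of 13 senescence genes. For the light reactions they were 8 of 47, for the Calvin cycle 3 of 21 and for photorespiration 4 of 14. No single gene passed limma's adjusted p over all 6 arrays: 0 probe sets were higher and 0 lower, with a lowest adjusted p of 0.375. At an unadjusted p under 0.05, 807 were higher and 678 lower, where 699 in all are expected by chance. The groups did not overlap for 742 probe sets higher and 812 lower in pho3, 11.1% of those tested against 10% by chance. Without wild-type replicate 1, 644 were higher and 117 lower, and with limma's array weights 2237 were higher and 2026 lower. The weights were lowest for wild-type replicate 1, at 0.367, and pho3 replicate 3, at 0.443. Such weights are estimated from the fit to the same labels, so arrays that deviate from their labelled group count less. The calls with weights thus depend on down-weighting these arrays and are no separate evidence for a difference.

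All 6 measured genes of the flavonoid and anthocyanin list had a higher mean in pho3, with a median log2 difference of 2.23 (camera adjusted p = 0.00777; adjusted p = 0.605 with an estimated correlation). DFR averaged 826 ± 295 in pho3 and 287 ± 443 in wild type (SD, n = 3). Its log2 difference was 3.12 (SE 1.22), with limma's adjusted p = 0.375. The anthocyanin glucosyltransferase AT4G14090, listed as UGT75C1, had signals of 510, 802 and 329 in pho3 and 525, 11.4 and 1.38 in wild type. UF3GT, the xylosyltransferase also called UGT79B1, differed by 2.76 and UGT78D2 by 1.70. None of the 6 genes passed limma's test over all genes, and 0 passed when adjusted over the list alone. Without wild-type replicate 1, 5 of the 6 passed over all genes and 6 over the list alone, and the median log2 difference was 3.32.

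All 3 measured starch synthesis genes had a higher mean in pho3, with a median log2 difference of 1.70 (camera adjusted p = 0.0379; adjusted p = 0.605 with an estimated correlation). APL3 averaged 449 ± 167 in pho3 and 184 ± 185 in wild type (SD, n = 3), and APL4 averaged 387 ± 149 and 135 ± 206. SBE2.2, a starch branching enzyme, averaged 630 ± 139 and 429 ± 130. The senescence list was also higher, with 3 of 3 genes and a median of 1.16 (camera adjusted p = 0.0487; adjusted p = 0.605 with an estimated correlation). Its members were the sugar transporter SAG29, also called SWEET15, at 2.42, and the transcription factors WRKY53, at 0.89, and WRKY6, whose wild-type mean lay under the 40th percentile and whose pho3 mean was at least 2.04-fold higher. With WRKY6 at that bound the median was 1.03. No member of either list passed limma's test over all genes or when adjusted over the list alone. Without wild-type replicate 1, APL3, APL4, SAG29 and WRKY53 passed over all genes, and all 3 members of each list passed over the list alone. The median log2 difference was then 2.50 for starch synthesis and 1.74 for senescence, the latter being the value of WRKY6 without its bound.

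Photosynthetic genes had lower means in pho3 by smaller amounts. All 8 measured light-reaction genes were lower (7 of 8, with a median of -0.08, after quantile normalization), with a median log2 difference of -0.24 (camera adjusted p = 0.0234; adjusted p = 0.605 with an estimated correlation). Among them were the photosystem I subunit PSAN at -0.33, PSBY at -0.32 and the antenna protein LHCB4.1 at -0.25. Without wild-type replicate 1, LHCB4.3 turned to 0.02. The 3 measured Calvin cycle genes were lower, with a median of -0.53 (camera adjusted p = 0.0487; adjusted p = 0.605 with an estimated correlation). Sedoheptulose bisphosphatase SBPASE differed by -0.60, phosphoribulokinase PRK by -0.53 and rubisco activase RCA by -0.23. The 4 measured photorespiration genes were lower, with a median of -0.58 (camera adjusted p = 0.0320; adjusted p = 0.605 with an estimated correlation). Hydroxypyruvate reductase HPR averaged 1717 ± 521 in pho3 and 2485 ± 356 in wild type (SD, n = 3), and AT1G11860, listed as the glycine decarboxylase subunit GLDT, averaged 988 ± 443 and 1497 ± 339. The groups overlapped: against the mean of the 6 arrays, the median of pho3 replicate 3 lay above that of the array labelled wild-type replicate 1 for photorespiration (0.26 and 0.01), the Calvin cycle (0.26 and -0.03) and the light reactions (0.09 and -0.04). In the same way the anthocyanin median was lower on pho3 replicate 3 than on that array (0.26 and 1.15). No member of the 3 lists passed limma's test over all genes, with or without wild-type replicate 1. Adjusted over the list alone, 0 members passed with all arrays, and 4 photorespiration genes passed without wild-type replicate 1.

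These list calls depended on the arrays used and on the preset correlation. At that correlation, other splits of the 6 arrays, which mix the lines by label, called 0 to 6 lists. With an estimated correlation and each array left out in turn, a setting added after the data had been seen, 0 lists passed (lowest adjusted p = 0.542 with an estimated correlation). At the preset correlation and with each array left out in turn, the anthocyanin list kept its call (camera adjusted p from 1.13e-05 to 0.0209), and each of the other 5 lists lost it without at least 1 array. The Calvin cycle list lost its call without wild-type replicate 1 (camera adjusted p = 0.0889), where the other 5 kept theirs at the preset correlation (adjusted p = 0.551 with an estimated correlation for all 6). Without pho3 replicate 1, 1 list was higher and 0 were lower. Without pho3 replicate 2 the senescence and Calvin cycle lists lost their calls (camera adjusted p = 0.0533 and 0.0731). Without wild-type replicate 2 the Calvin cycle list lost its call (camera adjusted p = 0.0712) and chlorophyll synthesis passed as lower (camera adjusted p = 0.0484; adjusted p = 0.675 with an estimated correlation). Without pho3 replicate 3 and without wild-type replicate 3, 1 list was higher in each case, and the Calvin cycle list was lost without wild-type replicate 3 (camera adjusted p = 0.0677). After quantile normalization the light-reaction and Calvin cycle lists lost their calls (camera adjusted p = 0.270 and 0.202), with RCA at -0.07, and the Calvin cycle list lost its call under 5 other settings too.

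**Figure D2:**
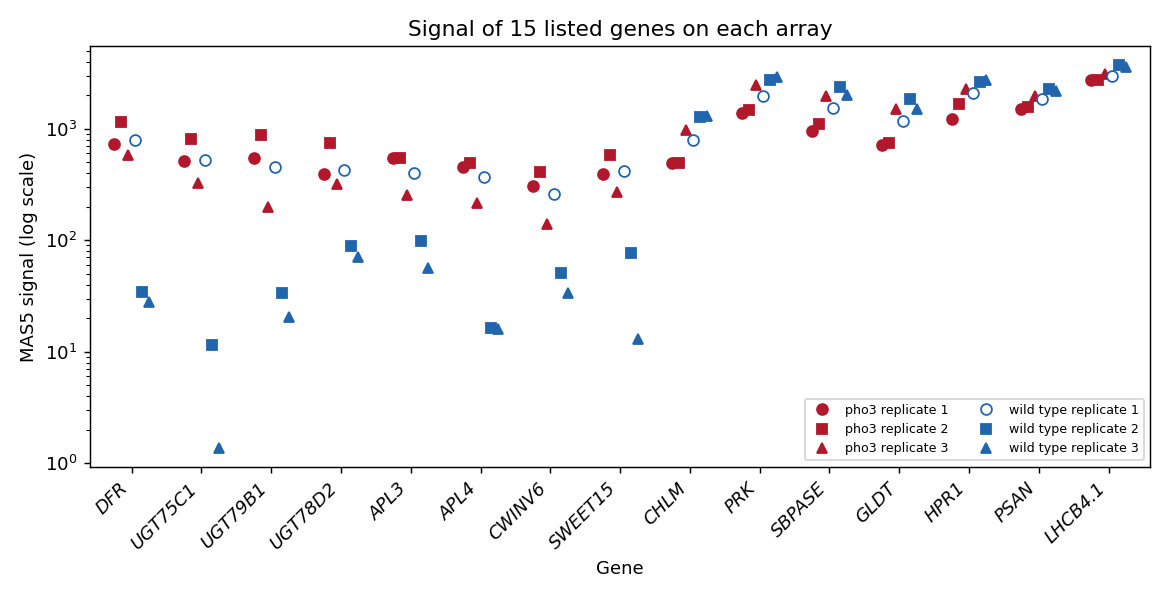
Each point is the MAS5 signal (log axis) of 1 listed gene on 1 array, for 15 genes, with red for pho3, blue for wild type and an open circle for the array labelled wild-type replicate 1. For DFR that array reads 799, within the pho3 range of 586 to 1155, and wild-type replicates 2 and 3 read 34.2 and 27.6.

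The other 7 lists tested did not pass. Of 3 starch breakdown genes the alpha-amylase AMY1 had the largest difference, 1.18, and the median was 0.10 (camera adjusted p = 0.441). Sucrose and sugar transport genes went both ways: cwINV6 differed by 1.76 and SWEET11 by 0.41, while the sucrose phosphate synthase ATSPS4F differed by -0.62. The list's median was -0.11 and its mean 0.20 (camera adjusted p = 0.789, direction up). All 4 chlorophyll synthesis genes were lower, with CHLM, the magnesium protoporphyrin methyltransferase, at -0.82 (camera adjusted p = 0.201). The 3 glycolysis genes were lower as deposited, with a median of -0.12 (camera adjusted p = 0.387). After quantile normalization 1 of 3 was lower (camera adjusted p = 0.916, direction up). The 3 pentose phosphate genes AT1G64190, AT3G02360 and AT5G41670 were higher, with a median of 0.20 (camera adjusted p = 0.203). The sugar-starvation genes IVD, MCCA and MCCB differed by 0.24, 0.16 and 0.03 (camera adjusted p = 0.441). Of the cold and abscisic acid genes, LTI30 differed by 1.29, COR15A by 0.54, COR47 by -0.12 and COR15B by -0.58 (camera adjusted p = 0.789). No member of these 7 lists passed limma's test over all genes or when adjusted over the list alone.

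Of lists with too few measured members for a set test, the plastid translocator AT5G17630, listed as XPT, differed by -0.69. SAG101 of salicylic acid defence differed by 0.70, and the jasmonate response genes PDF1.2 by -0.02 and THI2.1 by at least 1.12-fold. The guard cell marker FMA differed by -0.27. None of these 5 genes passed limma's test over all genes. AT5G17630 and SAG101 were each the only tested member of their list, so adjusting over the list alone leaves an unadjusted p. It was 0.0328 for AT5G17630 and 0.0532 for SAG101 (limma), and 0.0174 and 0.0187 without wild-type replicate 1. The lists for phenylpropanoid entry, flavonoid regulators, phosphate starvation, nitrogen assimilation, phloem, xylem, flower, seed and root had 0 tested members.

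Leaving out wild-type replicate 1 was planned as part of leaving out each array in turn; naming genes from that fit was decided after the data had been seen. In it, 644 probe sets rose and 117 fell in pho3, and 590 and 72 of them changed at least 2-fold. In the same 5 arrays, setting pho3 replicate 3 with wild-type replicates 2 and 3 called 2693 probe sets, against 761 by the labels. AT4G14090 rose at least 18.8-fold (limma adjusted p = 0.0114), and DFR rose 25.8-fold (limma adjusted p = 0.00277). AT1G76960 rose at least 35.9-fold and AT5G03350 at least 37.7-fold. AT5G52760 rose at least 9.21-fold and AT1G65690 at least 8.91-fold. AT2G23910, AT3G28510, AT2G44240, AT1G78410 and AT1G26420 rose by at least 1.57-fold to 3.86-fold. On the array labelled wild-type replicate 1, AT1G76960 read 848 and AT5G03350 read 1040, against 1.94 and 23.7 as the mean of wild-type replicates 2 and 3.

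In the same fit the expansin EXPA8 fell from a mean of 947 on wild-type replicates 2 and 3 to 214 in pho3, a log2 difference of -2.31 (SE 0.50, limma adjusted p = 0.0492). AT2G05540 fell from a mean of 182 to 29.2 (limma adjusted p = 0.0255). AT1G30250, AT5G66590, AT1G64380 and AT5G49100 fell by 2.26, 2.03, 1.95 and 1.79 on the log2 scale. The plastid ribosomal protein gene rpl36 fell by 1.71, AT1G76240 by 1.67, AT5G62730 by 1.57 and AT3G56060 by 1.49. Among listed genes AMY1, cwINV6, COR15A and LTI30 also rose, AMY1 3.72-fold and cwINV6 6.24-fold. For 637 of the 761 called probe sets, the array labelled wild-type replicate 1 read within the range of the 3 pho3 arrays, and for 0 within the range of the other wild-type arrays. It read between the ranges for 79. These counts are not like measures. The pho3 range spans 3 arrays and reaches toward wild type through pho3 replicate 3. The wild-type range spans 2 arrays, on probe sets whose calls favour a small spread within groups. An array lying between the groups could give such counts, so they do not tell which line it came from. Leaving out any other array gave 0 probe sets in each direction.

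The second comparison used the control probe sets for the 3-prime and 5-prime parts of transcripts, whose ratio rises with RNA degradation or short labelling products. The actin ratio of the first control set was 4.75, 5.24 and 3.46 on the pho3 arrays and 4.23, 2.18 and 2.26 on the wild-type arrays (exact permutation p = 0.2, two-sided). The smallest p that 3 against 3 arrays allow is 0.1. The other 5 ratios, from a second actin set and from GAPDH and ubiquitin, differed by between -0.06 and 0.05 on the log2 scale (exact permutation p between 0.5 and 0.9).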

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

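The fit without both wild-type replicate 1 and pho3 replicate 3 and the estimated correlation with each array left out were chosen after the data had been seen; the other alternatives were planned. Over quantile normalization, median centring, a pseudocount of 16, 3 other filters, 2 other variance priors and the replicate block, the count of called genes stayed at 0 in each direction. Array weights, lowest for wild-type replicate 1 and pho3 replicate 3, gave 2237 higher and 2026 lower, 947 and 573 of them at least 2-fold. The fit without both arrays gave 2547 higher and 2305 lower, 1253 and 867 at least 2-fold, and all 644 and 117 genes called without wild-type replicate 1 were among them. It keeps only the arrays at the ends of principal component 1, so a large count follows in part from that choice. All its arrays are also in the fit without wild-type replicate 1, so the overlap is no separate evidence. Leaving out 1 array in turn gave 0 to 644 genes higher and 0 to 117 lower, 0 to 590 and 0 to 72 at least 2-fold; only the fit without wild-type replicate 1 was above 0. The count of lists higher ranged from 1 to 3 and of lists lower from 0 to 3 over the arrays left out. Lists higher were 1 with the 60th percentile filter, 0 with an estimated correlation and 0 with fry. Lists lower were 1 with quantile normalization, 1 with no filter, 0 with an estimated correlation and 0 with fry. The Calvin cycle list lost its call with quantile normalization (adjusted p = 0.202), median centring (0.0708), no filter (0.0923), the 60th percentile filter (0.0510), the filter on the mean (0.0546) and eBayes without trend (0.0852). The light-reaction list lost its call with quantile normalization (0.270) and no filter (0.0596), the senescence list with eBayes without trend (0.0551) and starch synthesis with the 60th percentile filter (0.0506). The senescence list had too few members left under the 60th percentile filter. The replicate number as a block gave 0 genes higher and 0 lower (lowest adjusted p 0.192), 3 lists higher and 3 lower. At an unadjusted limma p under 0.05 the block gave 3040 probe sets, against 1485 without it. Deviations from the group mean correlated across probe sets at 0.388, -0.274 and 0.430 for same-numbered arrays. Differently numbered arrays reached 0.523, for pho3 replicate 2 and wild-type replicate 1. These correlations cannot decide whether the numbers pair the arrays, because the outlying arrays shape the group means.

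Values that turned sign were all of genes or lists that did not pass, and the cause was not tested. With quantile normalization TPI went to 0.0084 and GAPC2 to 0.040, and the glycolysis list turned up (adjusted p = 0.916). With the 60th percentile filter the abscisic acid and cold list turned down (adjusted p = 0.794). MCCB went to -0.042 with array weights, and MCCA and MCCB to -0.059 and -0.11 without both arrays. Over the arrays left out in turn, log2 differences ranged from -0.12 to 0.16 for MCCB, -0.29 to 0.41 for PWD, -0.24 to 0.32 for DPE1, -0.13 to 0.0053 for AT5G42740, -0.56 to 0.061 for PORB, -0.084 to 0.014 for GSA1, -0.35 to 0.50 for PDF1.2 and -0.061 to 0.68 for THI2.1. The adjusted p ranged from 0.162 to 0.812 for the starch breakdown list and from 0.209 to 0.950 for the abscisic acid and cold list. The 3-prime to 5-prime differences ranged from -0.045 to 0.073 for the second actin set, -0.022 to 0.15 for the first GAPDH set, -0.072 to 0.025 for the second, and -0.060 to 0.014 for the first ubiquitin set. Signals near the 40th percentile limit what can be said of dim genes such as AT1G26420.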

Other observations

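All tests in this part were chosen or given their limits after the results had been seen, except the count of other splits, which was planned, although its prediction was also written afterwards. Genes encoded in the plastid were lower in pho3 as a group: all 67 measured genes had a lower mean, with a median log2 difference of -0.35 (camera adjusted p = 9.87e-14 over 16 groups chosen after seeing the data, most of them by a shared symbol prefix; adjusted p = 0.626 with an estimated correlation). Among them rpl36 differed by -1.37, ndhH by -1.03, rps16 by -1.02 and ndhK by -0.95, while psbC and rpl32 differed by -0.10 and -0.07. After quantile normalization 54 of 67 were lower and the median was -0.24. The medians per array, against the mean of the 6 arrays, were -0.30, -0.23 and 0.04 for pho3 and -0.06, 0.31 and 0.24 for wild type. No member passed limma's test over all 6 arrays.

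The SWEET sugar transporters, with SAG29 (SWEET15) of the senescence list among them, went both ways, with 8 of 12 higher in pho3 (camera adjusted p = 0.595). Without wild-type replicate 1, SAG29 rose 12.6-fold, SWEET4 rose 5.96-fold, SWEET13 rose 5.62-fold and SWEET10 rose at least 1.60-fold, and SWEET2 and SWEET16, which did not pass, differed by -1.37 and -1.61. In the same fit the cytochrome P450 genes CYP71B23, CYP71B26 and CYP71B6, singled out after their values were seen, rose 5.97-fold, 2.91-fold and 1.81-fold. The 10 measured P450 genes with a CYP symbol did not pass as a group (camera adjusted p = 0.910 in that fit). None of the 16 groups other than the plastid-encoded genes passed with camera.

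The position of the array labelled wild-type replicate 1 near the pho3 arrays, and of pho3 replicate 3 between the groups, was weighed against 4 technical explanations. A plain exchange of these 2 labels was not settled. The 2 arrays would then come from different lines. Yet their spread against each other, 0.272, was smaller than that of either array against its supposed new group, 0.306 to 0.368. Both arrays lay between the ends, so a small spread between them does not tell which line each came from. The split with these 2 labels exchanged called 2973 genes, against 0 by the labels, but it follows from the same positions. A wrong label on the array labelled wild-type replicate 1 alone stays open, as its largest spread against a pho3 array was 0.310 and its smallest against a wild-type array 0.470. These spreads are the pattern to be explained and no separate support. The spread between pho3 replicates 1 and 2 was smaller, 0.243, than that of this array against either, 0.310 and 0.306. A wrong label on this array alone would also leave the position of pho3 replicate 3 unexplained. A mixture of RNA or plants of both lines stays open too. With genes picked on other arrays, the median position of the array labelled wild-type replicate 1 from the wild-type end (0) to the pho3 end (1) was 0.658 to 0.725. That of pho3 replicate 3 was 0.346 to 0.432, and genes higher and lower in pho3 differed by at most 0.0629 in position. Genes varied around these medians, with quartiles from 0.546 to 0.910 for the array labelled wild-type replicate 1 and 0.108 to 0.602 for pho3 replicate 3. How much of that is noise was not tested. An array between the ends for another reason could give such medians, so they do not decide for a mixture. RNA degradation was not settled, as the control ratios went both ways. In 1 of 6 control pairs, the first actin set, the array labelled wild-type replicate 1 had a 3-prime to 5-prime ratio above both other wild-type arrays. In that pair pho3 replicate 3 lay below both other pho3 arrays (4.75, 5.24 and 3.46 in pho3, and 4.23, 2.18 and 2.26 in wild type). The other 5 pairs did not show this order. In both GAPDH and both ubiquitin pairs the array labelled wild-type replicate 1 lay below both other wild-type arrays, against degradation of its RNA. The first GAPDH ratios in wild type were 1.23, 1.27 and 1.34, and the first ubiquitin ratios 1.63, 1.78 and 1.80. The limits for the mixture and degradation tests were set with these values already known, and no biological explanation was tested, since the labels give no group within a line.

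The 6 arrays split into 3 and 3 in 10 ways, too few for a share under 0.05. The split by label called 0 genes, so all 10 splits gave as many, and the highest other split called 2973. For genes changed at least 2-fold the real value was 0 and the highest other 1018, again with all 10 splits as large. The split with 2973 calls sets pho3 replicates 1 and 2 with wild-type replicate 1. It is the grouping with the labels of wild-type replicate 1 and pho3 replicate 3 exchanged. It restates the position of these arrays among the samples and is no separate evidence for it. For lists, 2 of the 10 splits, the split by label among them, gave as many calls as the real 6, and the highest other gave 6. The remaining splits called 4, 4, 3, 2, 1, 0, 0 and 0 lists. Camera at the preset correlation thus also called lists for groupings that mix the lines by label. Without wild-type replicate 1, the other 5 arrays also split in 10 ways: the labels called 761 genes, 662 of them at least 2-fold, and setting pho3 replicate 3 with wild-type replicates 2 and 3 called 2693 and 1104. Of lists, the labels then called 5, and the other splits 5, 4, 3, 3, 2, 1, 1, 0 and 0.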
